A study of Mus musculus with 12 samples.

How the data were processed

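Bulk RNA was sequenced from 12 tumour samples of the mouse pancreatic cancer line CR705, 6 WT and 6 AHRKO, with mRNA selected by poly-T beads and read on an Illumina instrument per the labels. The RNA protocol in the labels names tumours of WT or knockout CR705 cells, while the growth and treatment texts describe cultured cells with test compounds; all 12 samples were taken as tumours without a compound, since no sample label names one. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2, handled with SAMtools, counted with HTSeq and compared with DESeq2. The annotation, strandedness and counting settings are not given in the sources used here. The deposited table holds raw read counts per gene, as the authors gave them, and every value was checked to be a whole number of 0 or more.

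The table covers 43432 genes by Ensembl identifier. Symbols and mm10 coordinates were joined by identifier from GENCODE release M21, which matched 42462 genes holding at least 99.9% of each library's counts; 970 genes had no match. In 14411 genes every library had 0 counts. The 37 mitochondrially encoded genes had 0 counts in all libraries, so their share could not serve as a sign of RNA quality. The 10 most abundant genes took from 4.51% to 8.22% of a library's counts.

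Library totals ran from 14772343 to 35881469 counts. Libraries of the same group were compared pair by pair for duplicates: the lowest chi-squared per degree of freedom was 13.7, far above the value near 1 that resequencing the same library would give, so no pair agreed within sampling noise. Reads carry no molecular identifiers in the table, so depth covers counting error only, and the spread between libraries is the error used throughout.

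Genes were kept by edgeR's filterByExpr with the groups, which left 15449 genes, and libraries were scaled by TMM. AHRKO was compared with WT by edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F value. Counts scaled to a common library total (CPM) use the TMM-scaled totals, and logarithms use a prior count of 2. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The groups, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined.

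Named genes were Ahr, then the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and all 6 AHRKO libraries on the same side of the WT median. To these were added the 5 rises and 5 falls with the smallest p. From each gene list with a changed member up to 4 members with the smallest p were taken, and from lists without one up to 2. Predicted genes with only a model number, pseudogenes and variable segments of immunoglobulin or T cell receptor genes were passed over. Some genes that this rule takes are not reported here.

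For 35 gene lists a score was formed per library, the mean log2 CPM of the tested members. The lists covered AHR targets, the AHR complex and tryptophan-kynurenine genes, leukocytes as a whole, T, CD8 and cytotoxic, CD4 and regulatory, NK, B and plasma cells, macrophages and monocytes, neutrophils, dendritic cells, mast cells and eosinophils. Others covered chemokines for T cells and for myeloid cells, immune checkpoints, type I interferon, interferon gamma with antigen presentation, fibroblasts, endothelium, ductal, acinar and islet cells, skeletal muscle, keratinocytes, adipocytes and erythrocytes. The last covered epithelial-mesenchymal transition, proliferation, hypoxia, NRF2, complement, immediate early with heat shock genes, mitochondrially encoded genes and sex-linked genes. Scores were compared by an exact two-sided permutation test over all 924 assignments of the 12 libraries, in which the smallest possible p is 0.00216, with Benjamini-Hochberg adjustment over the 32 lists with at least 3 tested members. The mitochondrial list, with 0 of 13 members tested, the sex-linked list, with 1 of 5, and the islet list, with 2 of 14, were left out. Of 576 listed genes, 7 stand in more than 1 list (Ccl5, Ctla4, Ccr7, Gzma, Xcl1, Nqo1 and Slc7a5). Member counts are given over all genes tested and adjusted over the list alone. Each list was also tested with camera at an estimated and at a preset correlation of 0.01, and with fry.

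Alternatives for the gene test were DESeq2's Wald test, limma-voom with sample quality weights, edgeR's robust fit, median-of-ratios (RLE) and upper-quartile scaling, no filter and a stricter filter (at least 10 counts in 6 or more libraries and a mean log2 CPM of at least 1), a replicate block, and leaving out each library in turn. For the lists they also included z-scored and median scores. A fit with the pan-leukocyte score as a covariate was added after the data were seen.

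The pipeline was tested on simulated data with the same depths and spread. Of 99 simulated genes with a 2-fold change 54 were recovered, which is 54.5%, and of 97 with a 4-fold change 83, which is 85.6%, with 6 false calls among 15124 unchanged genes. All 10 lists shifted by 1.5 on the log2 scale and 0 of 20 unshifted lists were called. For the lists the added spread between libraries was set and not taken from the data. In the simulation changes of 2-fold were thus often missed, and changes under 2-fold were not simulated. Far fewer genes were changed there than were called in the data, so the shares recovered may not carry over. The 27983 genes below the filter were not tested.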

Results

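RNA was sequenced from 12 tumour samples of CR705, a mouse pancreatic cancer cell line. In 6 samples the cells were labelled wild type (WT), and in 6 they were labelled knockouts of the aryl hydrocarbon receptor (AHRKO). The receptor is a transcription factor that is activated by ligands and encoded by Ahr. WT replicates 1 to 6 had totals of 23901486, 35881469, 21864362, 19293174, 19764596 and 20388593 counts, and AHRKO replicates 1 to 6 had 18003434, 19944273, 14772343, 17964146, 15364660 and 16877540. Of 43432 genes in the count table, 15449 had enough counts to be tested. Nothing in the labels says that the replicates came from separate animals, so each p below measures only the spread between these samples.

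The comparison addresses whether tumours of cells labelled AHRKO differ from WT tumours in their gene expression, and in particular in the genes of immune cells. Ahr itself (ENSMUSG00000019256, mm10 chromosome 12, 35497974 to 35535038, minus strand) was measured at 112 ± 8.18 CPM (counts scaled to a common library total) in WT and 102 ± 30.6 CPM in AHRKO (mean ± SD, n = 6 per group). Single WT libraries had 114, 125, 113, 106, 110 and 101 CPM of Ahr, and single AHRKO libraries had 62.5, 94.0, 143, 75.2, 124 and 114. The log2 fold change of Ahr (AHRKO over WT) was -0.13 ± 0.17 (SE) and did not pass edgeR's quasi-likelihood test (adjusted p = 0.606). With limma-voom and sample quality weights it was 0.009 (adjusted p = 0.959). In 3 AHRKO libraries Ahr was above the WT median and in 3 below it. A knockout may leave its transcript in place, so these values do not check the genotype labels.

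AHRKO tumours had more transcripts of lymphocyte, antigen presentation and interferon-response genes than WT tumours. Cxcl9, a chemokine that attracts T cells, rose 26.3-fold, from 9.95 ± 16.6 to 259 ± 222 CPM (mean ± SD, n = 6 per group). Cd74, the invariant chain of MHC class II, rose 11.7-fold, from 122 ± 65.8 to 1432 ± 831. Among the genes that fell were Glp1r, an incretin receptor, from 46.2 ± 17.6 to 0.43 ± 0.20 CPM, and Cdkn2a, which encodes cell-cycle inhibitors, from 101 ± 13.2 to 2.26 ± 2.33. Each of these 4 genes lay on the same side of the WT median in 6 of 6 AHRKO libraries, with adjusted p of 0.00652 for Cxcl9, 0.000526 for Cd74, 1.45e-06 for Glp1r and 5.57e-05 for Cdkn2a (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment). Without WT replicate 4, the log2 fold change of Cxcl9 was 6.35 in place of 4.72, and without AHRKO replicate 1 that of Cdkn2a was -6.18 in place of -5.47.

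**Figure D1:**
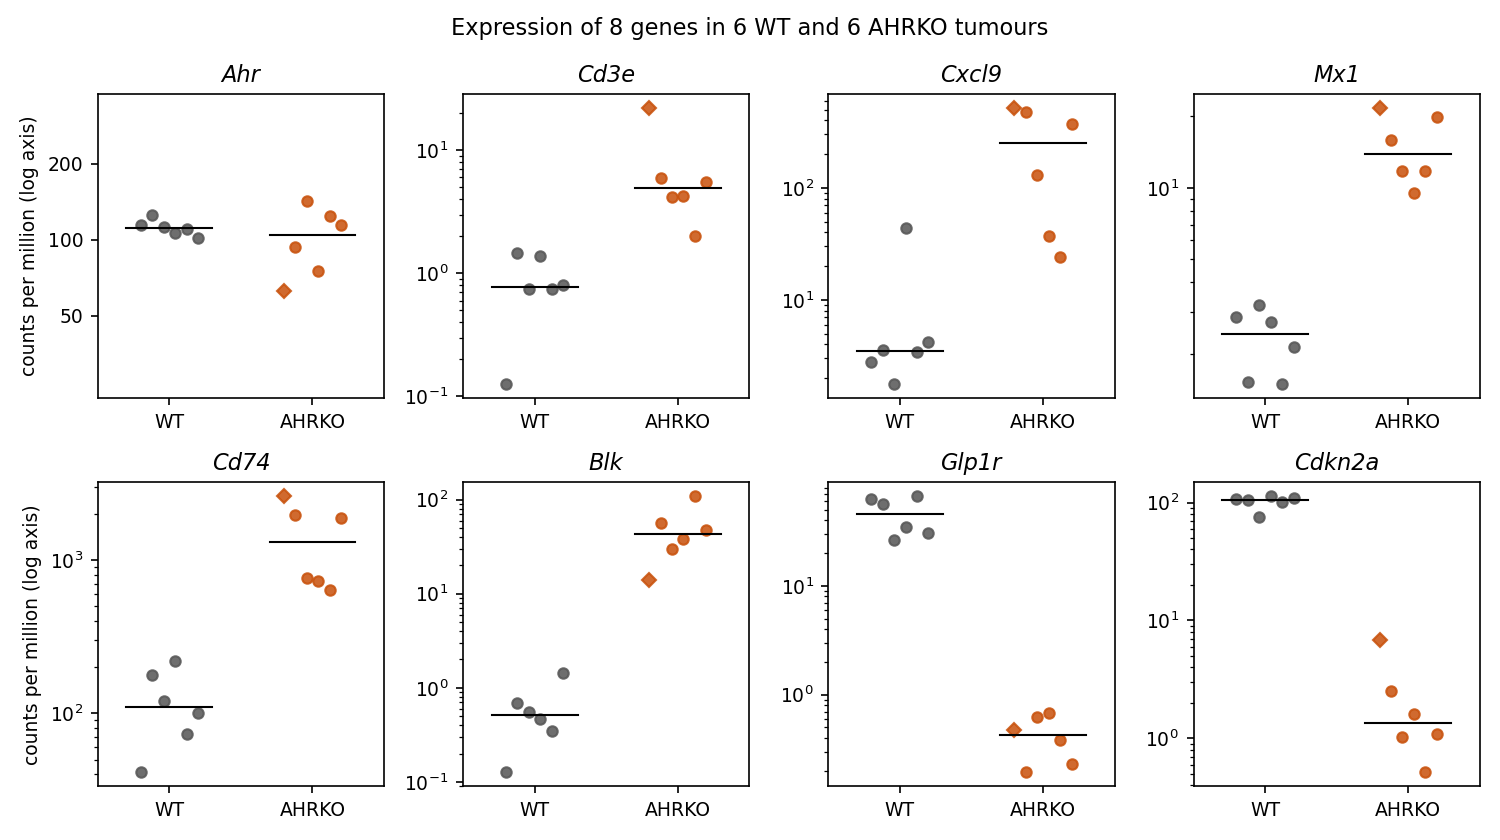
Read counts in CPM (log axis) of 8 genes in the 6 WT and 6 AHRKO libraries; each point is a library, the line is the group median and the diamond is AHRKO replicate 1. Ahr overlaps between the groups, while Glp1r and Cdkn2a are lower, and Cd3e, Mx1, Cd74 and Blk higher, in all 6 AHRKO libraries than in any WT library.

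In all, 2451 genes rose and 2106 fell in AHRKO tumours at an adjusted p under 0.05, among 15449 tested with edgeR's quasi-likelihood test. The median log2 fold change of all tested genes was 0.023. In a principal component analysis of the 1000 most variable genes, the first component held 57.0% of the variance. WT libraries lay between -46.5 and -22.2 on it, AHRKO replicate 1 at 77.7, AHRKO replicate 5 at -0.43, and the other 4 AHRKO libraries between 24.6 and 32.0. Without AHRKO replicate 1, 2980 genes rose and 2778 fell.

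The largest rises were those of Ighg2b and Ighg1, constant regions of IgG heavy chains, with log2 fold changes of 7.29 ± 1.51 and 7.25 ± 1.81 (SE). Blk, a Src-family kinase of B cells, followed at 6.34 ± 0.59, from 0.601 ± 0.448 to 49.2 ± 32.8 CPM. Ubd, an interferon-induced ubiquitin-like protein, rose by 4.97, and Gbp4, an interferon-induced GTPase, by 3.70. Also among the 12 largest rises were Slpi, a leukocyte protease inhibitor, at 4.35, the monocyte surface gene Ly6c2 at 4.34, Apol6 at 4.04, Slamf8 at 3.74, the chemokine gene Cxcl10 at 3.73 and Tesc at 3.64. Adjusted p for these 12 genes, Cxcl9 included, ran from 6.17e-05 for Blk to 0.0113 for Gbp4, with all 6 AHRKO libraries above the WT median. Ighg1, Ubd, Cxcl9, Cxcl10, Gbp4 and Slamf8 still overlapped between the groups, each higher in WT replicate 4 than in the lowest AHRKO library. Ighg1 was at 11.6 CPM in WT replicate 4 and 0.387 in AHRKO replicate 2, and Cxcl9 at 43.9 against 24.0 in AHRKO replicate 5. The rest of the 12 did not overlap. Several of these log2 fold changes depend on 1 library. Without AHRKO replicate 1 they were 5.90 for Ighg2b, 6.39 for Ighg1, 4.16 for Ubd, 2.99 for Slpi, 3.50 for Ly6c2 and 3.08 for Slamf8, and without WT replicate 4 they were 11.44 for Ighg1, 7.40 for Ubd and 4.99 for Gbp4. Without WT replicate 5, Ighg2b stood at 10.22. With limma-voom and sample quality weights Ighg1 was not called (adjusted p = 0.120, range over all settings 9.09e-05 to 0.120). Blk and Tesc were lowest among AHRKO libraries in replicate 1, where the pan-leukocyte score was highest.

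The largest fall was that of Lrp2, the endocytic receptor megalin, by 7.01 on the log2 scale, from 44.0 ± 16.4 to 0.346 ± 0.479 CPM, and Glp1r fell by 6.75 ± 0.37 (SE). Eno1b, an enolase gene that is a near-identical copy of Eno1, so that their reads can be shared, fell by 6.29 ± 0.23, from 109 ± 18.6 to 1.40 ± 0.456. Next came Klhl1 at -5.77, Nrk at -5.75, the growth factor receptor gene Fgfr4 at -5.63, Cdkn2a at -5.47 ± 0.50, the microvillar cadherin gene Cdhr2 at -4.43, the synaptotagmin gene Syt14 at -4.24, the neuronal pentraxin gene Nptx1 at -4.16, the steroid hydroxylase gene Cyp21a1 at -3.63 and the imprinted gene Rtl1 at -3.16. Their adjusted p ran from 1.3e-08 for Eno1b to 0.00253 for Cyp21a1, with all 6 AHRKO libraries below the WT median. Without AHRKO replicate 5, Lrp2 stood at -8.05, without AHRKO replicate 4, Cdhr2 stood at -5.08, and without AHRKO replicate 1, Cdkn2a stood at -6.18.

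The 5 rises with the smallest p were Znrf2, a ubiquitin ligase, at a log2 fold change of 1.09 (adjusted p = 4.2e-06), Nub1, an interferon-inducible regulator of NEDD8, at 0.85, the sodium channel gene Scn8a at 3.59, Rapgef3, an exchange factor activated by cyclic AMP, at 1.25, and Fam43a at 1.01. Beside Eno1b, Glp1r and Nptx1, the falls with the smallest p were the histone deacetylase gene Hdac9 at -2.40 (adjusted p = 5.78e-06) and the deubiquitinase gene Otud4 at -1.33 (adjusted p = 1.5e-05, edgeR's quasi-likelihood test). All 6 AHRKO libraries lay on the same side of the WT median for each. Many genes of some chromosomes shifted together: the median log2 fold change was -0.31 over 826 tested genes of chromosome 8, -0.24 over 524 of chromosome 12, 0.21 over 1164 of chromosome 7, 0.23 over 604 of chromosome 15 and 0.33 over 475 of chromosome 16. Otud4 lies on chromosome 8, Fam43a on chromosome 16, Ly6c2, Apol6, Scn8a and Rapgef3 on chromosome 15, and Ighg2b, Ighg1, Rtl1, Hdac9 and Ahr on chromosome 12. Of the genes named from lists, Rac2 and Cthrc1 lie on chromosome 15, Mx1 on chromosome 16, Cmpk2, Sdc1 and Hsp90aa1 on chromosome 12, and Coro1a, Nkg7, Ncr1, Cd22, Spib, Itgax, Arnt2 and Il4i1 on chromosome 7.

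Genes shared by all leukocytes rose together. All 14 tested pan-leukocyte genes rose over all genes tested, and 14 when adjusted over the list alone. Among them were Cd52 at a log2 fold change of 2.33, the actin regulator gene Coro1a at 2.02 and the GTPase gene Rac2 at 2.02. The pan-leukocyte score, the mean log2 CPM of the list, was higher by 1.54 in AHRKO (adjusted p = 0.016, exact permutation test; adjusted p = 0.525 with an estimated correlation), and 5 of 6 AHRKO libraries lay above the highest WT library. AHRKO replicate 1 stood apart at a score of 6.95, against 4.13 to 5.37 in the other AHRKO libraries and 3.15 to 4.18 in WT. Without it the difference was 1.20 (adjusted p = 0.0208, exact permutation test).

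T cell genes followed the same direction: 17 of 20 rose, and 18 when adjusted over the list alone. They included Cd3e, a chain of the T cell receptor complex, at 3.04 on the log2 scale (2.30 without AHRKO replicate 1), and the transcription factor gene Tcf7 at 0.55. Among AHRKO libraries Tcf7 was lowest, at 44.4 CPM, in replicate 1, where the T cell score was highest. The T cell score was higher by 1.79 (adjusted p = 0.016, exact permutation test; adjusted p = 0.525 with an estimated correlation) and above the highest WT library in 5 of 6 AHRKO libraries. Among genes of CD8 and cytotoxic lymphocytes, 9 of 12 rose, 9 also when adjusted over the list alone, such as the granule gene Nkg7 at 3.75, the chemokine gene Ccl5 at 3.44 and the transcription factor gene Runx3 at 1.80. Their score was higher by 2.26 in AHRKO, in 5 of 6 libraries above all WT (adjusted p = 0.016, exact permutation test; adjusted p = 0.525 with an estimated correlation). Genes of CD4 helper and regulatory T cells rose in 7 of 12 cases, over all genes and when adjusted over the list alone, with Cd4 at 2.19, Foxp3, the regulator of regulatory T cells, at 1.98, and Ctla4 at 2.11. The score of that list was higher by 0.89 (adjusted p = 0.0154, exact permutation test; adjusted p = 0.525 with an estimated correlation), with 5 of 6 AHRKO libraries above all WT. It was not called with fry (adjusted p = 0.0678). In the NK cell list 8 of 10 genes rose, 9 when adjusted over the list alone, with the receptor genes Klrk1 at 3.24 and Ncr1 at 2.84, and a score higher by 1.77 in AHRKO and above all WT in 5 of 6 libraries (adjusted p = 0.016, exact permutation test; adjusted p = 0.525 with an estimated correlation). That score was not called with fry (adjusted p = 0.0534).

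AHRKO replicate 1 had the highest score of all libraries in each of these lymphocyte lists. Without it the differences were 1.40 for T cells (adjusted p = 0.0266), 1.82 for CD8 and cytotoxic lymphocytes (adjusted p = 0.0323), 0.67 for CD4 helper and regulatory T cells (adjusted p = 0.0208) and 1.33 for NK cells (adjusted p = 0.0297), all by exact permutation tests. Single genes moved more: without AHRKO replicate 1, Nkg7 was at 2.89, Ccl5 at 2.44, Cd4 at 1.28, Foxp3 at 1.26, Ctla4 at 1.43, Klrk1 at 2.18 and Ncr1 at 1.89. Without WT replicate 4, Nkg7 was at 4.53. The count of NK cell genes that rose was 5 without WT replicate 2, 5 or 6.

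Genes of antibody-forming cells showed the largest list difference. Of 11 tested plasma cell genes 8 rose and 1 fell, 9 and 1 when adjusted over the list alone. Mzb1, a chaperone of immunoglobulin assembly, was at 4.19 and the receptor gene Tnfrsf13b at 1.76, while Sdc1, which epithelial cells also express and which was chosen after its value was seen, was at -0.56. The plasma cell score was higher by 3.09 (adjusted p = 0.0154, exact permutation test; adjusted p = 0.525 with an estimated correlation), above all WT in 5 of 6 libraries. It was not called with fry (adjusted p = 0.0756). B cell genes rose in 7 of 9 cases, also when adjusted over the list alone, with Cd22, an inhibitory receptor, at 2.21, the receptor component gene Cd79b at 2.99, and the transcription factor gene Spib at 2.72. The B cell score was higher by 2.05, in 6 of 6 AHRKO libraries above all WT (adjusted p = 0.0154, exact permutation test, and adjusted p = 0.525 with an estimated correlation). Blk, a member of this list, was at 56.2 CPM in AHRKO replicate 2 and 109 in AHRKO replicate 5, against at most 1.43 in WT. These libraries had the lowest B cell scores in AHRKO, 1.52 and 2.005, against a highest WT score of 1.22. The separation in 6 of 6 may therefore rest on Blk, and a score without it was not formed. Without AHRKO replicate 1, which had the highest score in both lists, the plasma cell difference was 2.69 (adjusted p = 0.0198) and the B cell difference 1.79 (adjusted p = 0.0139, exact permutation tests). Without that library Mzb1 was at 3.43, Tnfrsf13b at 1.17, Cd79b at 2.17 and Spib at 1.88.

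Genes of several myeloid cell types rose too, and AHRKO replicate 1 had the highest score in each of their lists. Dendritic cell genes rose in 13 of 16 cases, 13 also when adjusted over the list alone, including Itgax, which encodes CD11c, at 1.77, and Xcr1 and Batf3, genes of cross-presenting dendritic cells, at 3.24 and 2.55. Their score was higher by 1.54 in 6 of 6 AHRKO libraries above all WT (adjusted p = 0.0154, exact permutation test; adjusted p = 0.525 with an estimated correlation), and by 1.28 without AHRKO replicate 1 (adjusted p = 0.0139). Macrophage and monocyte genes rose in 15 of 21 cases, 16 when adjusted over the list alone, with the Fc receptor gene Fcgr1 at 1.81, the monocyte chemokine receptor gene Ccr2 at 1.91 and the complement gene C1qc at 1.60. The score was higher by 1.16, above all WT in 5 of 6 libraries (adjusted p = 0.0323, exact permutation test; adjusted p = 0.525 with an estimated correlation). That call ended without AHRKO replicate 1 (0.88, adjusted p = 0.0539) and equally without WT replicate 1, 4, 5 or 6 or AHRKO replicate 2, 4 or 6, with adjusted p of at most 0.0646, and with fry (adjusted p = 0.0601), and 9 genes rose without WT replicate 4 or 6. Mast cell and eosinophil genes rose in 8 of 11 cases, 9 when adjusted over the list alone, such as the mast cell protease genes Cpa3 at 1.91 and Mcpt4 at 1.85, while the receptor gene Il5ra fell by 3.66 (-4.25 without AHRKO replicate 4). Their score was higher by 1.34 (adjusted p = 0.0198, exact permutation test; adjusted p = 0.525 with an estimated correlation), above all WT in 5 of 6 libraries, and by 1.17 without AHRKO replicate 1 (adjusted p = 0.0346).

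Neutrophil genes rose in 6 of 14 cases, 6 also when adjusted over the list alone, among them Acod1, the itaconate-forming enzyme of activated myeloid cells, at 2.49 (1.85 without AHRKO replicate 1). The neutrophil score was 1.09 higher in AHRKO, which did not pass (adjusted p = 0.053, exact permutation test), with 2 of 6 AHRKO libraries above all WT. It passed with camera at the preset correlation of 0.01 (adjusted p = 0.00523; adjusted p = 0.525 with an estimated correlation) and without WT replicate 3, at 1.32 (adjusted p = 0.0173), and was 0.79 without AHRKO replicate 1 (adjusted p = 0.0935). The number of neutrophil genes that rose was 1 without WT replicate 5, 2 without WT replicate 1 or 4, and 3 without WT replicate 6 or AHRKO replicate 1 or 4.

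**Figure D2:**
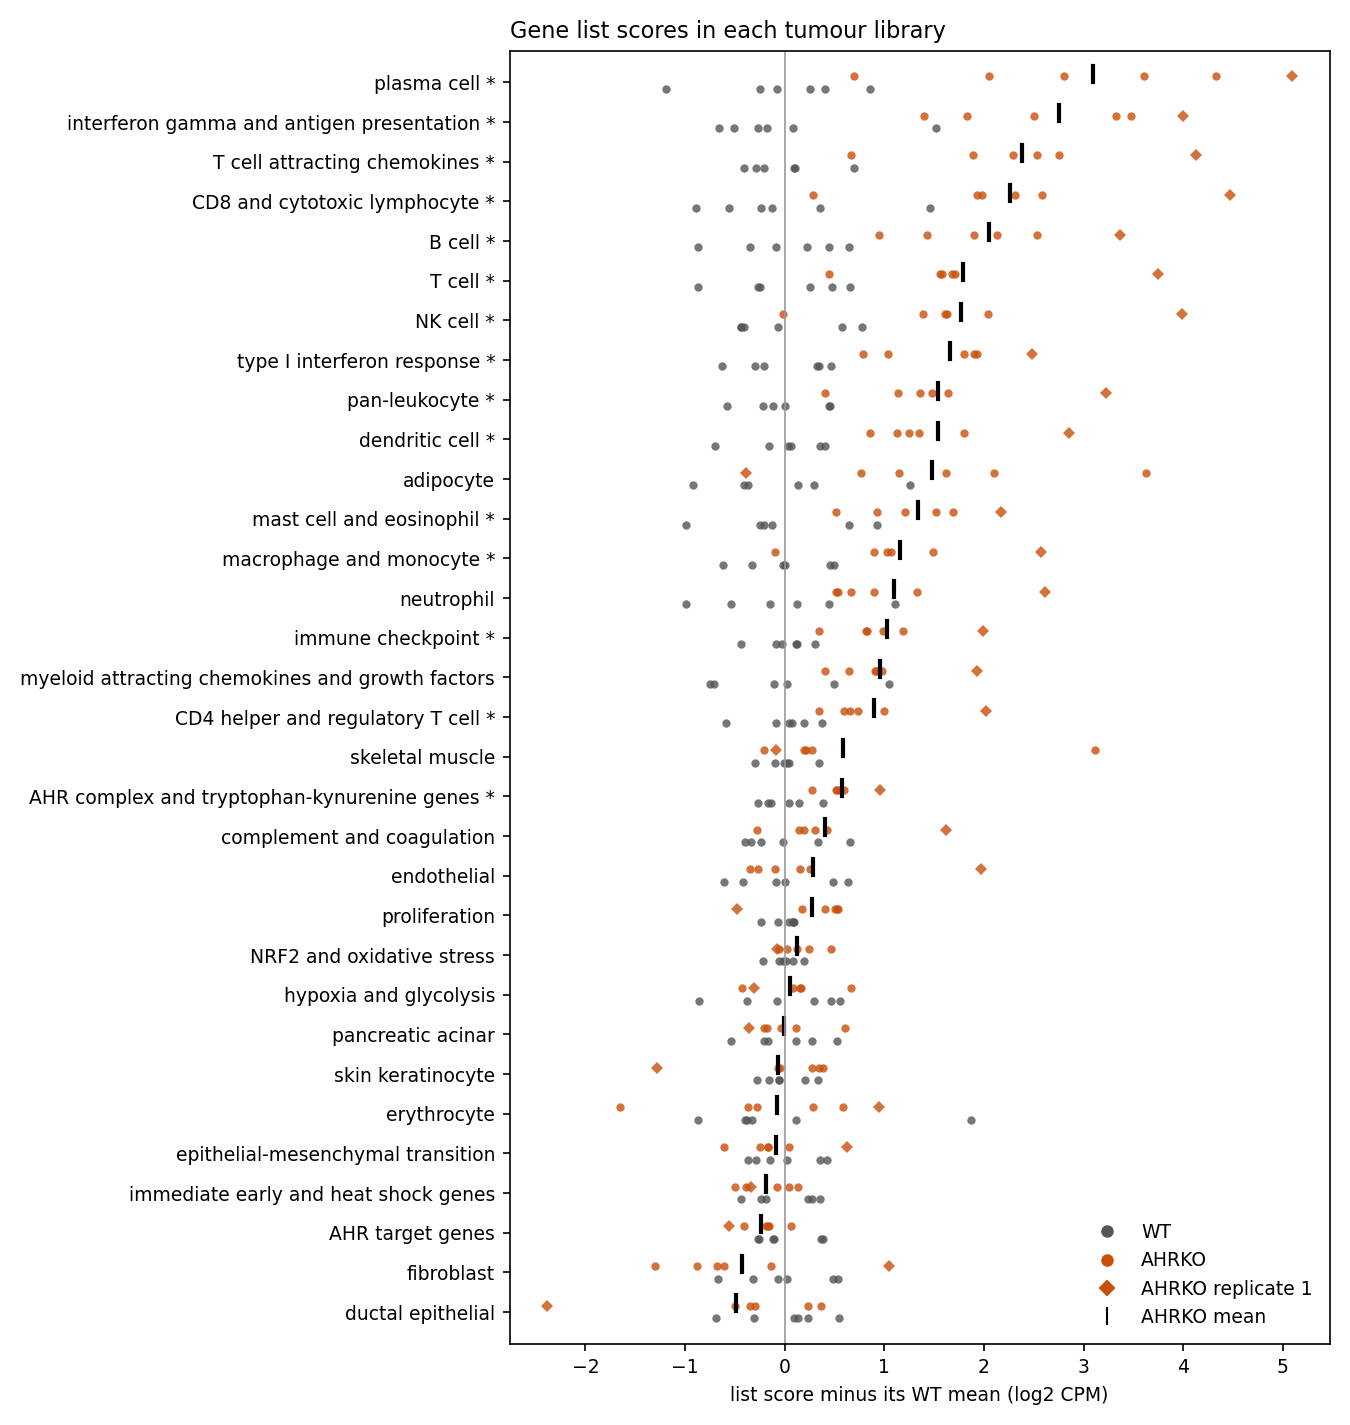
Scores of the 32 tested gene lists (mean log2 CPM) in each library, as the difference from the WT mean of the list; points are libraries, the bar is the AHRKO mean, the diamond is AHRKO replicate 1 and a star marks an adjusted exact p under 0.05. The plasma cell list has the largest AHRKO mean, at 3.09, and the type I interferon list is higher in 6 of 6 AHRKO libraries than in any WT library.

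Chemokines that attract T cells rose with the cells' own genes: 11 of 12 rose, and 12 when adjusted over the list alone, including Cxcl9 and Cxcl10 above, their receptor gene Cxcr3 at 3.53 (2.53 without AHRKO replicate 1) and Cxcl16 at 0.99. The score was higher by 2.38 (adjusted p = 0.0154, exact permutation test; adjusted p = 0.525 with an estimated correlation), above all WT in 5 of 6 AHRKO libraries, and by 2.03 without AHRKO replicate 1 (adjusted p = 0.0198), whose score was the highest. Immune checkpoint genes rose in 10 of 16 cases, while 12 rose and 1 fell, Cd276 at -0.20, when adjusted over the list alone (Cd276 was chosen after its value was seen). Lag3 was at 1.82, Pdcd1, which encodes PD-1, at 2.59, and its ligand gene Pdcd1lg2 at 2.42. Their score was higher by 1.02 in AHRKO, with 6 of 6 libraries above all WT (adjusted p = 0.0154, exact permutation test; adjusted p = 0.525 with an estimated correlation), and by 0.83 without AHRKO replicate 1 (adjusted p = 0.0139). In the list of chemokines and growth factors for myeloid cells 6 of 16 rose and 1 fell, 9 and 1 when adjusted over the list alone: the monocyte attractant gene Ccl2 was at 1.54, Csf1, the macrophage growth factor gene, at 1.12, and the cytokine gene Lif at -1.07. Lif was not called with limma-voom and sample quality weights (adjusted p = 0.0828, range over all settings 0.00052 to 0.0828). The score of that list was 0.96 higher in AHRKO, which did not pass (adjusted p = 0.053, exact permutation test), with 1 of 6 libraries above all WT. It passed with camera at the preset correlation of 0.01 (adjusted p = 0.00434; adjusted p = 0.525 with an estimated correlation) and without WT replicate 3, at 1.17 (adjusted p = 0.0173), and was 0.77 without AHRKO replicate 1 (adjusted p = 0.0911).

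All 23 tested genes of the type I interferon response list rose, 23 also when adjusted over the list alone and at least 22 without any 1 library, such as the antiviral genes Mx1 at 2.70, Oas3 at 2.79 and Cmpk2 at 2.07 (adjusted p = 0.000102, 0.00144 and 0.00127, edgeR's quasi-likelihood test, 6 of 6 AHRKO libraries above the WT median). Their score was higher by 1.66, with 6 of 6 AHRKO libraries above all WT (adjusted p = 0.0154, exact permutation test; adjusted p = 0.525 with an estimated correlation). All 24 genes of the interferon gamma and antigen presentation list rose too, 24 also when adjusted over the list alone and at least 22 without any 1 library: H2-DMb1 and H2-DMa, which load peptides onto MHC class II, were at 3.07 and 2.70, Cd74 at 3.55, and the immunoproteasome gene Psmb8 at 2.95. The score was higher by 2.76 (adjusted p = 0.0154, exact permutation test; adjusted p = 0.525 with an estimated correlation), above all WT in 5 of 6 AHRKO libraries. Without AHRKO replicate 1, the highest library in both lists, the differences were 1.49 (adjusted p = 0.0139) and 2.51 (adjusted p = 0.0208).

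Known AHR target genes went both ways, and few passed the test. Of 12 tested, the fatty acid transporter gene Cd36 rose by 1.73 on the log2 scale (adjusted p = 0.0218, edgeR's quasi-likelihood test, 6 of 6 AHRKO libraries above the WT median), the glucuronosyltransferase gene Ugt1a6a by 1.05 (adjusted p = 0.0359, 5 of 6), and Ahrr, the receptor's repressor, fell by 1.00 (adjusted p = 0.0476, 5 of 6 below). Adjusted over the list alone, 2 rose and 2 fell, the other fall being that of the retinol-esterifying enzyme gene Lrat at -1.85. Cd36 was not called without AHRKO replicate 4 (adjusted p = 0.0519), Ugt1a6a not without any of 8 libraries (WT replicate 1, 2, 4, 5 or 6, or AHRKO replicate 4, 5 or 6) and Ahrr not without any of 11 (each except AHRKO replicate 1). Without AHRKO replicate 1, 4 rose and 3 fell. Cyp1b1, a classical target, was at 0.067 (adjusted p = 0.940), and Tiparp, chosen like Cyp1b1 after its values were seen, at -0.39 (adjusted p = 0.241). The list score differed by -0.24 and did not pass (adjusted p = 0.256, exact permutation test), with 2 of 6 AHRKO libraries below all WT. It was -0.17 without AHRKO replicate 1 (adjusted p = 0.371). Scored by the median member of each library the difference was 0.22 (adjusted p = 0.480), while the median log2 fold change of the members was -0.25. Cyp1a1, Cyp1a2, Il22, Ugt1a6b and Gsta2 had too few counts to be tested.

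Genes of the receptor complex and of the tryptophan-kynurenine pathway, which forms AHR ligands, went both ways. Of 17 tested 6 rose and 3 fell, 8 and 4 when adjusted over the list alone. The kynurenine pathway gene Kmo was at 2.29 and the amino acid oxidase gene Il4i1 at 1.51. In contrast, Arnt2, which encodes a partner of the receptor, was at -1.99 and the chaperone gene Hsp90aa1 at -0.69. Arnt, which encodes the receptor's main partner and was chosen after its value was seen, was at -0.24 (adjusted p = 0.0378, edgeR's quasi-likelihood test, 6 of 6 AHRKO libraries below the WT median). The score of this list was higher by 0.57 (adjusted p = 0.0154, exact permutation test; adjusted p = 0.525 with an estimated correlation), above all WT in 5 of 6 libraries, and by 0.49 without AHRKO replicate 1 (adjusted p = 0.0231), whose score was the highest. It was not called with camera at the preset correlation of 0.01 either (adjusted p = 0.245). Without WT replicate 5, 3 of the genes rose. In a fit with the pan-leukocyte score as a covariate, chosen after the data were seen, 1 of the 17 rose and 1 fell. Their median log2 fold change was 0.319 in that fit, against 0.265 without the covariate. The covariate correlates with genotype at 0.762, so the fit does not separate leukocyte RNA from genotype.

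Lists of stromal and tumour cell markers showed no difference that passed the exact permutation test over all 12 libraries. The fibroblast score differed by -0.43 (adjusted p = 0.366, exact permutation test; called with camera at the preset correlation of 0.01, adjusted p = 0.0295; adjusted p = 0.685 with an estimated correlation): Fbln2 was at -0.62 and Cthrc1 at -0.76, and these 2 of 20 genes fell, 1 when adjusted over the list alone. Without AHRKO replicate 1, which had the highest fibroblast score, the difference was -0.72 (adjusted p = 0.0448) and 12 genes fell. Without any other library except WT replicate 1 or 4, only 1 fell. The endothelial score differed by 0.28 (adjusted p = 0.711, exact permutation test), 0 of 15 genes changed, and the difference was -0.06 without AHRKO replicate 1 (adjusted p = 0.810), which was the highest library at 7.28. In the ductal epithelial list 1 of 20 genes rose and 1 fell, Msln, which encodes mesothelin, at -0.98, the same numbers when adjusted over the list alone. The ductal score differed by -0.49 (adjusted p = 0.421, exact permutation test) and by -0.11 without AHRKO replicate 1 (adjusted p = 0.725), whose score of 3.52 was the lowest. Without that library 2 ductal genes rose and 2 fell, and 2 also fell without WT replicate 5 or AHRKO replicate 2 or 5. Pancreatic acinar genes had a score difference of -0.01 (adjusted p = 0.961, exact permutation test), against a median log2 fold change of 0.26 over the members and 0.095 without WT replicate 1, and 0 of 4 changed. Of 14 islet genes only 2 had enough counts to be tested, Chga at 0.42 (adjusted p = 0.753) and Pcsk1 at 0.56 (adjusted p = 0.323), so that list has no score. Chga was at 16.4 CPM in AHRKO replicate 1 and at most 3.07 in the other AHRKO libraries. Without replicate 1 it turned to -1.01 (adjusted p = 0.292), and with quality weights to -0.11 (adjusted p = 0.918).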

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

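The tests of the leukocyte score against stroma, of the data without AHRKO replicate 1, of the ductal list and of Mtap were chosen only after the results they address were seen, as were the tests of each chromosome and the fit with the leukocyte score as a covariate. A library is listed here when its gap to the nearest library of its group, divided by the range of the group, passed the 95% value of Dixon's test for 6 libraries. Chance does this in about 1 in 20 groups, so 6.5 of the 130 groups tested would be listed by chance, and 18 were. Of the 18, 7 are in AHRKO replicate 1.

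Among the library totals, WT replicate 2 was the highest, with a gap of 72.2% of the range. In AHRKO replicate 1 the score was highest for endothelial genes (74.0%), for complement and coagulation genes (63.4%) and for chemokines and growth factors of myeloid cells (62.5%). The same library was lowest for ductal epithelial genes (68.6%), skin keratinocyte genes (72.9%), proliferation genes (65.0%) and, among single genes, Syt14 (70.2%). AHRKO replicate 2 was highest for skeletal muscle genes (85.5%), AHRKO replicate 5 for Fam43a (65.0%) and AHRKO replicate 6 for Rtl1 (69.7%). Within WT, replicate 4 was highest for the interferon gamma and antigen presentation list (65.8%), Ighg1 (70.9%), Cxcl9 (73.4%) and Gbp4 (78.2%). WT replicate 5 was highest for Ighg2b (69.1%), and WT replicate 3 was highest for erythrocyte genes (64%) and lowest for Cdkn2a (68.8%).

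Immune and interferon genes were higher in AHRKO tumours, with a pan-leukocyte difference of 1.54 (adjusted p = 0.016, exact permutation test; adjusted p = 0.525 with an estimated correlation). Lower depth of the AHRKO libraries is argued against, since with every library thinned to the smallest total the T cell difference was at least 1.72 in 10 draws, against 1.79 at full depth. A lower share of tumour cells alone would raise stromal genes as much, but the leukocyte score minus the mean of the fibroblast and endothelial scores was higher in AHRKO by 1.61 (exact two-sided p = 0.00216, the smallest that the design allows), and AHRKO replicate 1 alone is argued against by a pan-leukocyte difference of 1.20 without it (exact p = 0.00649). Chance as the source of the 4557 changed genes is argued against: only 1 of 100 splits of the libraries, the real one, gave as many. The highest other split gave 1427, and 462 splits are possible. The splits treat the libraries as independent, which the labels do not state. They cannot address a chance difference between the WT and AHRKO cell populations. The pattern may be a biological one, but the labelled loss of the receptor and any other difference between the WT and AHRKO cell populations coincide with the groups. The labels do not give the number of knockout clones.

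Genes of whole chromosomes shifted together, with a median log2 fold change of -0.31 on chromosome 8 (adjusted p = 0.00722, exact permutation test of the chromosome's mean, 330 of 826 genes lower and 54 higher). On chromosome 16 the median was 0.33 (adjusted p = 0.00722, same test, 180 of 475 higher and 18 lower). Of 20 chromosomes 14 passed this test, so the p alone does not set these 2 apart. Chromosome 13 passed with a median of -0.014, but parts of it moved in opposite directions. In windows of 10000000 bases its medians were -0.246, -0.195, -0.240 and -0.167 up to position 40000000. From there to 60000000 they were 0.235 and 0.179, and later windows lay between -0.059 and 0.128. These windows were not tested. GC content and gene length are argued against by a chromosome 8 median of -0.32 once their trends were taken out (95% bootstrap interval over genes, which are not independent, -0.35 to -0.29). With the leukocyte score as a covariate the median was -0.26 (-0.31 to -0.23), as predicted if more immune cell RNA were not the cause. That covariate correlates with genotype at 0.762, so the fit does not fully separate the 2. A different copy number in the AHRKO tumour cells is a candidate explanation: the proximal and the distal genes of chromosome 8 both shifted, with medians of -0.36 and -0.27 and with 78.5% and 75.3% of 413 genes each below 0. On the X chromosome Xist, the RNA of the inactive X, fell from 1714 ± 520 to 539 ± 79.3 CPM (adjusted p = 0.000196, edgeR's quasi-likelihood test, 6 of 6 libraries below the WT median). The 6 genes that escape X inactivation had a median log2 fold change of -0.32, against -0.053 over 475 other X-linked genes. Among them Kdm6a at -0.757, Kdm5c at -0.495 and Eif2s3x at -0.468 passed the same test. Ddx3x at -0.138, Pbdc1 at -0.164 and Mid1 at 0.068 did not. Fewer X chromosomes in these cells could lower such genes, but they did not all fall. Male cells are argued against by at most 1 count of 4 Y-linked genes in any library. No DNA was analysed here, so the copy number stays a hypothesis, and whether it came with the knockout or from growth of separate cell populations was not tested.

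Cdkn2a fell by 5.47 on the log2 scale and its neighbour Cdkn2b, chosen after its values were seen, fell from 39.3 ± 7.32 to 4.71 ± 3.43 CPM (adjusted p = 0.000433, edgeR's quasi-likelihood test, 6 of 6 libraries below the WT median). A lower share of tumour cells is argued against, since the ductal epithelial list differed by only -0.49 (95% interval -1.36 to 0.38), far from the Cdkn2a value. Loss of 1 unbroken interval from Ifne, a neighbour near the floor that went from 1.02 to 0.00806 CPM, to Cdkn2b is argued against by Mtap, which lies between them and was at -0.046 (95% interval -0.55 to 0.46). Other neighbours, chosen after their values were seen, fell. Wincr1 and Gm12602, between Ifne and Mtap, were at -1.10 and -1.49 (adjusted p = 0.0128 and 0.00453, edgeR's quasi-likelihood test). Dmrta1, beyond Cdkn2b and near the floor, was at -2.61 (adjusted p = 0.00633). Focad and Klhl9 passed as falls too, while Hacd4 and Mrpl48-ps lay above 0 and did not pass. A wider loss around Cdkn2a cannot be told apart from none, because the other 10 tested genes within 1 Mb, Ifne left out, had a median of -0.45 with an interval from -1.10 to 0.009. From 80000001 to 90000000 on chromosome 4, Cdkn2a and its neighbours included, the median over 33 tested genes was -0.312, with 14 lower and 0 higher. In the window from there to 100000000 it was 0.158. A shift of these windows was not tested. A short deletion or silencing of Cdkn2a and Cdkn2b in the AHRKO cells could give the values of these genes, and neither was tested. A short deletion of these genes alone would not span Wincr1, Gm12602 or Dmrta1.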

How the results depend on the processing

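The fit with the pan-leukocyte score as a covariate was chosen after the data were seen. With the replicate block 1114 genes rose and 1240 fell, of which 1104 and 1228 were also called without it; the cause was not tested. The replicate numbers showed no pairing of the libraries, though a weak pairing cannot be excluded. Correlations of the same number across groups ran from -0.468 to 0.029, and each number correlated more with another number. With the replicate block the exact sign-flip test has a smallest p of 0.0312, which gave an adjusted p of 0.0769 for the pan-leukocyte, T cell, CD8 and cytotoxic, type I interferon and interferon gamma lists, so this lost call follows from the 64 sign patterns and says nothing about stability. The other 10 called lists were not called there either, with adjusted p up to 0.118. With camera at an estimated correlation the adjusted p was 0.525 for each of those 5 lists. The correlation between their genes was estimated at 0.67 to 0.926. With camera at the preset correlation of 0.01, far below those estimates, all 5 were called, so the camera result depends on the correlation used. Camera compares the genes of a list with all other genes, while the permutation test compares the list score between groups. In all other settings those 5 lists kept their call, with adjusted p from 7.54e-14 to 0.0396, and the AHR target list stayed uncalled (0.186 to 0.550). Counts of higher genes ran from 2155 without a filter to 3260 with DESeq2, and of lower genes from 1884 without a filter to 2948 with quality weights. Between 1849 and 2451 of the higher genes, and 1732 and 2106 of the lower genes, were shared with the counts reported above. Leaving out 1 library gave 1822 to 2980 higher and 1632 to 2778 lower genes. With upper-quartile scaling 49.9% of changed genes were higher, against 53.8%. With the leukocyte covariate, which correlates with genotype at 0.762, 1914 rose and 2136 fell, 883 and 797 of them shared. Of 128 called named genes 19 lost their call without at least 1 library and 41 with the replicate block. The 27983 genes below the filter, among them Cyp1a1, were not tested.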

Other observations

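The tests of gene families and of the leukocyte covariate were chosen after the gene table was seen. Some gene families rose beyond the share expected among 15449 tested genes. The Ifi family of interferon-inducible genes had 13 of 16 members that rose (adjusted p = 6.33e-06, Fisher's exact test over 231 families in both directions), with a median log2 fold change of 1.47. In the Clec family of C-type lectins, receptors of myeloid cells among them, 12 of 19 rose (adjusted p = 0.000963, Fisher's exact test), with a median of 1.45, and 9 of 16 chemokines of the Ccl family rose (adjusted p = 0.0380), with a median of 1.49. No family passed for falls. Fisher's test treats the genes as independent, although such genes move together, so these p do not measure the spread between tumours.

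Of 24 proliferation genes 7 rose, 8 when adjusted over the list alone, such as Pcna, the replication clamp, at a log2 fold change of 0.46, the helicase gene Mcm3 at 0.72 and the spindle motor gene Kif11 at 0.73. The proliferation score was 0.28 higher in AHRKO (adjusted p = 0.233, exact permutation test), with 5 of 6 libraries above all WT and AHRKO replicate 1 lowest; without that library it was 0.43 higher (adjusted p = 0.0139) and 17 genes rose. It was called with camera at the preset correlation of 0.01 (adjusted p = 0.00394; adjusted p = 0.685 with an estimated correlation). Without WT replicate 1, 3 rose, and without WT replicate 4, 5 or 6 or AHRKO replicate 3 or 4, 4 rose. In the NRF2 list 5 of 16 genes rose and 1 fell, the same when adjusted over the list alone. The cystine transporter gene Slc7a11 was at 1.34 (adjusted p = 0.000183, edgeR's quasi-likelihood test, 6 of 6 AHRKO libraries above the WT median), G6pdx at 0.45 and Osgin1 at 0.74, while the glutathione reductase gene Gsr, on chromosome 8 like Osgin1, was at -0.77. The NRF2 score differed by 0.12 (adjusted p = 0.366, exact permutation test). Scored by the median member of each library it passed at 0.32 (adjusted p = 0.0139; adjusted p = 0.685 with an estimated correlation), while the median log2 fold change of the members was 0.068. In that list 3 genes rose without WT replicate 2, 3, 5 or 6, and 2 fell without AHRKO replicate 5. Hypoxia and glycolysis genes had a score difference of 0.053 (adjusted p = 0.929), against a median log2 fold change of -0.042 over the members and -0.12 without WT replicate 5, and 0 of 20 changed; 1 rose without WT replicate 2 or 3.

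Of 15 immediate early and heat shock genes 1 rose and 3 fell, also when adjusted over the list alone: Dnajb1 was at -0.52, Junb at -0.55 and Ier2 at -0.39, all on chromosome 8, and Jun at 0.27. The score differed by -0.19 (adjusted p = 0.366, exact permutation test). Ier2 was not called without WT replicate 1, 2 or 5 or AHRKO replicate 2 or 6, and Jun was called without WT replicate 2 or 3 or AHRKO replicate 1 or 5 but not without any other library. In the complement and coagulation list 2 of 15 genes rose and 1 fell, 1 and 1 when adjusted over the list alone. The tissue factor gene F3 was at -1.30 (adjusted p = 0.00217, edgeR's quasi-likelihood test, 6 of 6 AHRKO libraries below the WT median), and the complement genes C3 and C1s1 were at 1.63 (1.01 without AHRKO replicate 1) and 1.32. C3 was not called without WT replicate 1, 4, 5 or 6, and C1s1 was called without WT replicate 3 or AHRKO replicate 3, 4 or 5 only; without WT replicate 3, 5 genes rose and without AHRKO replicate 5, 6 rose. The score differed by 0.40 (adjusted p = 0.360, exact permutation test), and by 0.156 without AHRKO replicate 1 (adjusted p = 0.559). Epithelial-mesenchymal transition genes had a score difference of -0.09 (adjusted p = 0.792, exact permutation test). It was 0.017 without AHRKO replicate 5 and -0.229 without AHRKO replicate 1 (adjusted p = 0.303 for the latter). Of 19 genes Tgfbi, at 1.23, and Twist1, at 0.50, rose and Fn1, at -0.49, fell, with 0 calls when adjusted over the list alone. Those 3 calls each ended without 8 or more single libraries, and without AHRKO replicate 1, 0 rose and 6 fell.

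Markers of other tissues varied by library. Skeletal muscle genes were high in AHRKO replicate 2, at a score of 4.20 against at most 1.42 in any other library. The score differed by 0.58 (adjusted p = 0.366, exact permutation test), and by only 0.079 without AHRKO replicate 2. Of 7, the enolase gene Eno3 rose by 1.12, and Mylpf, at 2.49, was called but was at 0.77 and not called without AHRKO replicate 2; 3 rose when adjusted over the list alone. Mylpf also lost its call without any single WT library, and 4 genes rose without AHRKO replicate 1. Adipocyte genes were high in AHRKO replicate 4, at 5.46 against at most 3.94 elsewhere, and the score was 1.48 higher in AHRKO (adjusted p = 0.0731, exact permutation test), 1.85 without AHRKO replicate 1 (adjusted p = 0.0231). It also passed without WT replicate 5 (adjusted p = 0.0462), with camera at the preset correlation of 0.01 (adjusted p = 0.0132; adjusted p = 0.525 with an estimated correlation) and as a mean of z-scored values. Of 12 adipocyte genes 4 rose, 8 when adjusted over the list alone, including Fabp4 at 1.96 and Pnpla2 at 0.71; 8 rose without AHRKO replicate 1, 7 without WT replicate 5, and 2 without WT replicate 2 or 6 or AHRKO replicate 4. The keratinocyte score differed by -0.067 (adjusted p = 0.943), and passed at -0.42 when scored by the median member of each library (adjusted p = 0.016; adjusted p = 0.685 with an estimated correlation), with Krt10 at -0.52 and Lor at -0.89, the 2 of 5 genes that fell, also when adjusted over the list alone. Lor was not called without WT replicate 1, 2, 3 or 5 or AHRKO replicate 2, 3 or 5, and without AHRKO replicate 1, 2 keratinocyte genes rose and the score difference was 0.18 (adjusted p = 0.301). The erythrocyte score differed by -0.082 (adjusted p = 0.943, exact permutation test) and by 0.29 without WT replicate 3 (adjusted p = 0.608) and 0.23 without AHRKO replicate 2 (adjusted p = 0.728), and 0 of 5 genes changed.

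In a fit with the pan-leukocyte score as a covariate, 5 of 23 type I interferon genes and 8 of 24 interferon gamma and antigen presentation genes rose, with median log2 fold changes of 1.10 and 1.55. In that fit 1 of 14 pan-leukocyte genes rose, 17 of 24 proliferation genes rose and 20 of 20 fibroblast genes fell. The covariate correlates with genotype at 0.762, so these counts do not separate them.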
